A study of Mus musculus with 8 samples.

How the data were processed

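Liver gene expression was measured on 8 Affymetrix arrays, 1 per mouse, in female C57BL/6 mice. Per the labels' protocols, 4 mice received the antisense oligonucleotide SPC3833 intravenously at 5 mg/kg on 3 consecutive days and 4 mice received saline. The labels give 2 times for the measurement: the study design places it on day 4, and the treatment protocol places sacrifice on day 3, counted from the day of the first dose. Per the labels' protocols, total liver RNA was isolated with Trizol, purified on RNeasy columns, and amplified and labelled with biotin by a whole-transcript sense-strand assay.

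The authors deposited 1 table of log2 expression values for 22361 probe sets on the 8 arrays, with no missing value and a range from 0.88 to 14.18. That the scale is log2 was read from this range. The affy package is named in the submitters' processing notes without a version. The background correction, the normalization, the probe set definition and the genome build were not given in the sources used here. Each probe set carries 1 Ensembl mouse gene ID, and probe sets are called genes below. The quartiles of the 8 arrays were similar but not identical. The number of arrays, 4 per group, limits the precision. The median standard error of a log2 fold change was 0.106, and the median half-width of its 95% interval was 0.231.

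The files do not pair the Ensembl IDs with gene names. The gene table used here has 49997 entries, of which 0 hold an Ensembl ID, so 0 of the 22361 IDs matched. The 28 lists of pathway genes and cell type markers fixed before the data were examined were therefore not analysed here. Planned tests of gene length and of circadian clock genes were not analysed either. A planned value for Apob could not be looked up by name. Any probe set of Apob among the 22361 was tested without its name. The plan had restricted the comparison to probe sets paired with 1 gene symbol. As no probe set was paired with a symbol, all 22361 were tested instead.

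Groups were taken from the titles of the samples. Arrays of a group shared at most 0.134% of identical values, and each was counted as a separate animal, as the labels describe biological replicates. SPC3833 and saline were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend), two-sided, on the deposited values, with no filter on dim genes and no covariate. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors and 95% intervals are those of the moderated fit. Genes named singly were also tested with a two-sided exact permutation test over all assignments of the 8 arrays, whose outcome the rule for named genes fixes in advance. Figures were drawn with matplotlib 3.10.9.

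The rule for named genes, written before the data were examined, took the genes with the largest rise and the largest fall among those past the threshold whose SPC3833 values all lay above or all lay below the saline values. Because the gene table used here gave no names for the IDs, the first 2 in each direction are given. The fit was tested on simulated data made from these arrays, with 200 of 22361 genes changed in each of 20 simulations. It recovered 5.4% of the genes changed by 0.30 on the log2 scale, 61.5% of those changed by 0.585, 91.3% of those changed by 1 and 99.5% of those changed by 2. Of the genes it called, 5.12% had not been changed. The simulated noise was normal and independent between genes, with the same spread in both groups and no difference between whole arrays. The real arrays do differ as a whole, so these rates may not hold for them.

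The alternatives planned before the data were examined were quantile normalization, centring on the median or on the 75th percentile, filters on dim genes, an intensity trend, robust variances, array weights, the replicate number as a block, leaving out each array in turn, and other thresholds. After the data were seen, a fit without SPC3833 arrays 2 and 4 and a fit without the genes above 13 in saline were added. The tests of technical explanations were chosen after an exploratory fit had been seen, except the count of other splits for the number of genes changed. Several of their bounds were then rewritten once first values were known. One test, of a ceiling on the brightest genes, was replaced, and the value of the first test is given beside that of the second. Another pattern weighed at first, the balance of rises and falls, was exchanged for the differences between SPC3833 animals, and its values are given among the alternatives.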

Results

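Expression was measured in the livers of 8 female C57BL/6 mice, 4 given SPC3833 and 4 given saline. SPC3833 is an antisense oligonucleotide, a short synthetic nucleic acid made to bind a complementary RNA. The labels used here do not name its target. Mean log2 expression lay between 5.77 and 5.80 on 7 arrays and was 5.88 on SPC3833 array 2. Pairs of arrays correlated, across genes, at 0.990 to 0.993 within saline, at 0.988 to 0.991 within SPC3833 and at 0.981 to 0.989 between the groups.

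**Figure D1:**
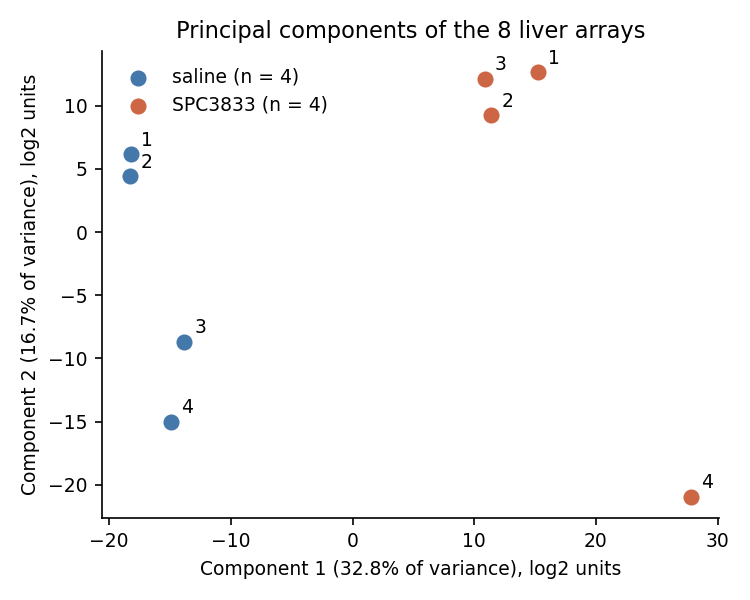
Principal components of the 8 arrays over 22361 genes, in log2 units, with 1 point per mouse and its replicate number. Component 1 (32.8% of the variance) separated the groups, with saline between -18.2 and -13.9 and SPC3833 between 10.8 and 27.8, and SPC3833 array 4 lay lowest on component 2 (16.7%) at -20.9.

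The comparison asked which liver genes differed between mice given SPC3833 and mice given saline. The largest fall was in ENSMUSG00000020609, one of the brightest genes of the saline livers (percentile 99.8). Its log2 expression was 12.46 ± 0.02 (SD, n = 4) with saline and 9.69 ± 0.24 (SD, n = 4) with SPC3833. It was 6.79-fold lower with SPC3833, with a log2 fold change of -2.76 (SE 0.114, 95% interval -3.01 to -2.51, limma adjusted p = 2.22e-07). The next largest fall was in ENSMUSG00000031196, from 7.78 ± 0.22 to 5.16 ± 0.39 (SD, n = 4 each). This gene was 6.14-fold lower, with a log2 fold change of -2.62 (SE 0.176, 95% interval -3.00 to -2.23, limma adjusted p = 9.50e-06).

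The named rises were smaller and had larger standard errors. ENSMUSG00000057465 rose from 6.82 ± 0.43 to 8.80 ± 1.20 (SD, n = 4 each), a log2 fold change of 1.98 (SE 0.466, 95% interval 0.96 to 2.99, limma adjusted p = 0.0386). SPC3833 array 4 held its highest value, 10.55, against 7.89 to 8.58 on the other SPC3833 arrays. ENSMUSG00000091028 rose from 8.37 ± 0.96 to 10.17 ± 0.58 (SD, n = 4 each), a log2 fold change of 1.80 (SE 0.411, 95% interval 0.91 to 2.70, limma adjusted p = 0.0329). Its groups were barely apart: saline values ran from 7.23 to 9.27, and the lowest SPC3833 value was 9.34. One further gene rose by 1.98 but its groups overlapped, so it was passed over. For ENSMUSG00000020609, ENSMUSG00000031196, ENSMUSG00000057465 and ENSMUSG00000091028 alike, the two-sided exact permutation p was 0.0286, the smallest that 4 against 4 animals can give. This p was fixed by the rule for naming genes, which took only genes whose groups did not overlap, and is no separate evidence.

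Both named falls passed the threshold under all 19 alternative fits, with adjusted p up to 1.33e-05 for ENSMUSG00000020609 and 0.000551 for ENSMUSG00000031196. ENSMUSG00000057465 did not pass in 9 of the 19, with log2 fold changes of 1.82 to 2.18 in those 9, and ENSMUSG00000091028 did not pass in 8, with 1.42 to 1.80. Over all 19, their adjusted p ranged from 0.00756 to 0.128 and from 0.0116 to 0.195. Without SPC3833 arrays 2 and 4, an alternative chosen after the data were seen, the log2 fold change of ENSMUSG00000057465 was 1.21 and it passed (adjusted p = 0.0392).

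**Figure D2:**
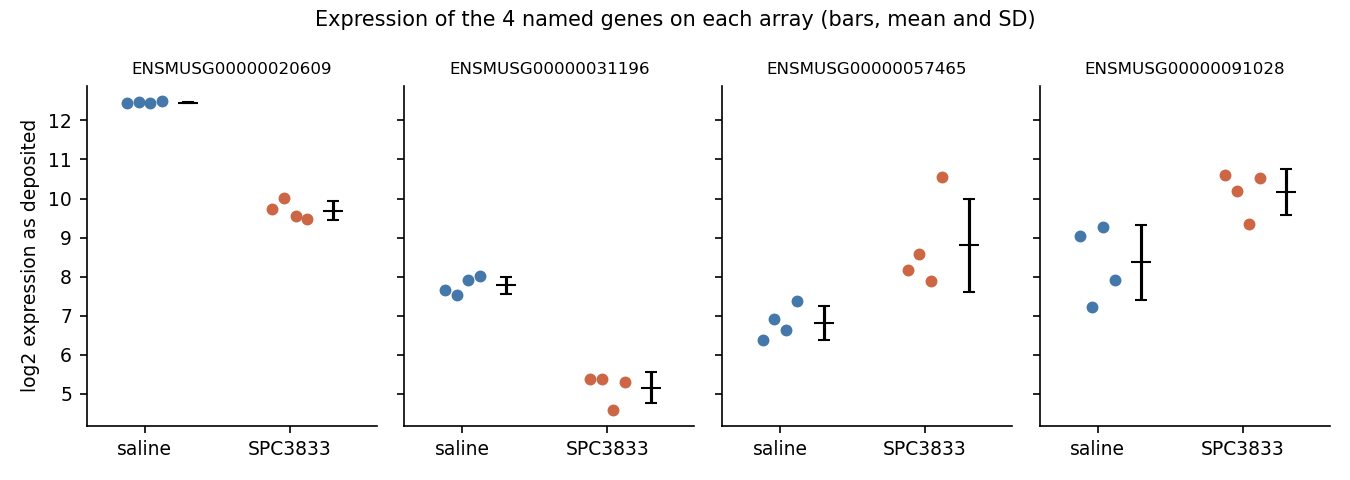
Log2 expression as deposited of the 4 named genes, with 1 point per mouse and, beside the points, the mean and SD of each group (n = 4). ENSMUSG00000020609 and ENSMUSG00000031196 were lower on every SPC3833 array than on any saline array, and ENSMUSG00000057465 and ENSMUSG00000091028 were higher.

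Of 22361 genes, 911 (4.07%) changed at the adjusted threshold, 521 higher and 390 lower with SPC3833. The unadjusted p was under 0.05 for 3846 genes. The balance of the directions depended on the scaling: 454 higher and 612 lower after quantile normalization, 276 and 487 after centring on the median, 439 and 531 after centring on the 75th percentile. The median log2 fold change of all genes was 0.03. The groups did not overlap for 2611 genes (11.7%), against 2.86% expected by chance, and 899 of the 911 changed genes were among them.

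Large falls were more numerous than large rises. Among changed genes, 50 were at least 2-fold lower and 25 at least 2-fold higher, and 8 were at least 4-fold lower against 0 at least 4-fold higher. Regardless of p, 54 genes were at least 2-fold lower and 35 at least 2-fold higher. The median size of the log2 change was 0.59 for the genes that fell and 0.51 for those that rose. The number of large rises was 9 without SPC3833 array 4, and 15 without saline array 2.

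Changed genes lay mostly among the brighter ones. Among the dimmest 25% of genes by mean expression 0.411% changed, 11 higher and 12 lower. The next 25% had 42 higher and 26 lower (1.22%), and the 25% above those 132 higher and 107 lower (4.28%). Of the brightest 25%, 10.4% changed, 336 higher and 245 lower, and these held 31 of the 50 large falls and 11 of the 25 large rises.

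Leaving out 1 array moved the number of changed genes by more than 1.5 times for 6 of the 8 arrays. It was 512, 467, 546 and 575 without saline array 1, 2, 3 and 4, and 567 and 576 without SPC3833 array 1 and 4. Without SPC3833 array 3 it was 762, and without SPC3833 array 2 it was 967, more than the 911 with all arrays. Each of these fits had fewer animals, and the part of this in the lower counts was not tested.

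**Figure D3:**
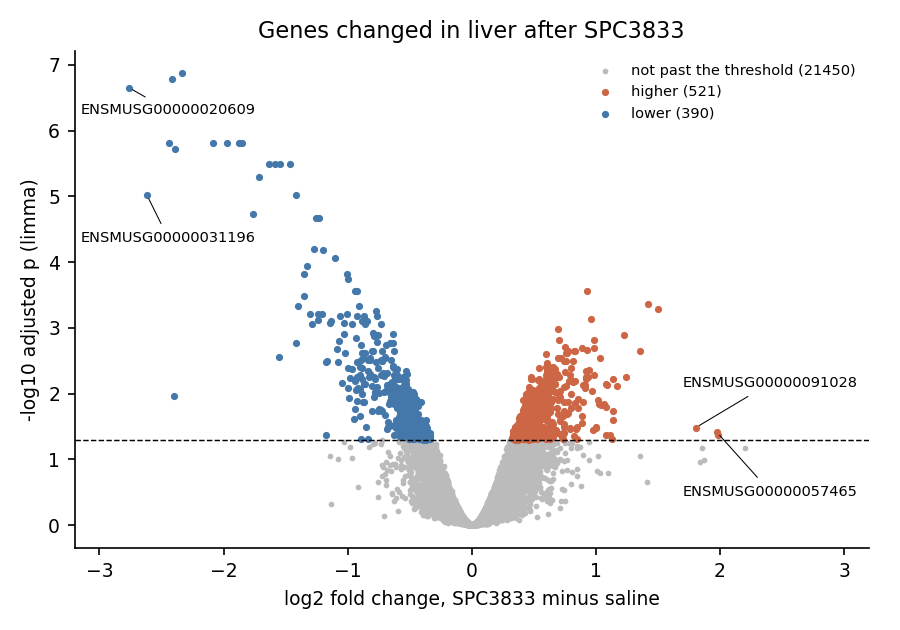
Log2 fold change of each of 22361 genes (SPC3833 minus saline) against -log10 of its limma adjusted p, with the threshold of 0.05 as a dashed line. Points past it are the 521 genes that were higher and the 390 that were lower, with the 4 named genes marked.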

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

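All tests weighed here were chosen after the arrays had been seen, apart from the count of splits for genes changed. Of the 26 sets of 4 values examined for a single array set apart, 3 held one, and chance gives about 1 in 20.

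The highest value on SPC3833 array 4 was 13.20, against 14.13 to 14.17 on the other SPC3833 arrays. Its correlation with the mean of the other SPC3833 arrays, across genes, was 0.991, against 0.993 to 0.994 for the others. ENSMUSG00000031196 was at 4.58 on SPC3833 array 3, against 5.29 to 5.39 on the other SPC3833 arrays, all below every saline array.

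The 30 genes above 13 in saline lay lower on SPC3833 array 4 than on the other SPC3833 arrays, by a median of -0.72 on the log2 scale. A single factor for the whole array is argued against, since genes between 8 and 9 in saline deviated by a median of -0.0486. A ceiling of the scan, scaled down on this array, stays open: the slope of this array on the saline mean above 13 was 0.672 (95% interval 0.468 to 0.876), below the 1.05 to 1.14 of the other arrays. Its interval ended just short of that of SPC3833 array 1 (from 0.876) but overlapped those of arrays 2 (from 0.793) and 3 (from 0.817). An earlier test of the same idea, the SD of the deviation over those genes, gave 0.194. The deviation also grew from -0.11 to -0.40 between 9 and 13. Over the 2521 genes between 8 and 13 in saline, the slope of this array was 0.897 (95% interval 0.881 to 0.914). The other SPC3833 arrays had 0.984 to 0.995. These genes lie below the highest value of this array, so a ceiling alone does not account for them. A brightness-dependent difference in normalization may act as well, as may a difference between animals.

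For the 911 genes changed, only the real grouping, 1 of the 35 splits of the 8 arrays, gave as many, the smallest share that 35 splits can give. The highest of the other splits gave 1. Those splits mix SPC3833 and saline arrays, which widens the spread within each side and can lower their counts. With 35 splits, chance as the source of the 911 cannot be excluded. The 521 rises, the 390 falls, the 50 large falls and the 25 large rises are parts of the 911, so their splits (also 1 of 35 each, highest other 1) add no separate evidence.

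Large falls outnumbered large rises by 50 to 25, a ratio of 2. Offsets between the arrays are argued against, as the lowest ratio over 3 other scalings was 2.89 (exact binomial lower bound 1.69, taking genes as independent, which they are not). The part of single arrays stays open: the ratio was 1.43 without SPC3833 array 3 and 5.78 without SPC3833 array 4. Rises that vary more between mice may also miss the threshold more often, and without the p threshold the ratio was 1.54 (lower bound 0.990), which leaves this open. A response of the liver to SPC3833 made mostly of falls at this size is therefore one of several open explanations.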

How the results depend on the processing

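Without SPC3833 arrays 2 and 4 and without genes above 13 in saline are alternatives chosen after the data were seen. Of the 911 genes, none turned sign in any of the 19 alternative fits that tested it. This was largely fixed in advance. The filters, the intensity trend, the robust variances and the replicate block leave a log2 fold change as it is. For the 899 genes whose groups did not overlap, leaving out arrays cannot turn the sign. The filters on the median, the 25th percentile and genes above 13 tested 820, 888 and 910 of them, and all of these stayed past the threshold. In the fits that tested all 911, 48 to 50 of the 50 large falls but 13 to 25 of the 25 large rises stayed past it. The cause of the shifts below was not tested. In some of these fits fewer genes or arrays entered, and the part of this was not tested either.

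The share of rises among changed genes was 57.2% as deposited, 42.6% after quantile normalization, 36.2% after centring on the median, 45.3% after centring on the 75th percentile, 42.6% at adjusted p under 0.01, 48.0% at 1.5-fold or more and 36.9% without SPC3833 arrays 2 and 4. Leaving out 1 array gave 43.2% to 60.1%, under 50 without SPC3833 array 2 (43.2%), saline array 1 (46.9%) and saline array 2 (46.7%). Quantile normalization gave 612 lower, and centring on the median 276 higher.

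Genes above the median alone gave 1552 changed, 932 higher and 620 lower. Adjusted p under 0.01 gave 296, 126 and 170, adjusted p under 0.1 gave 1582, 956 and 626, and a change of 1.5-fold or more gave 383, 184 and 199. Without SPC3833 arrays 2 and 4, 545 changed and 201 were higher. Without the genes above 13 in saline, 910 changed. Large rises numbered 15 after quantile normalization, 14 after centring on the median, 16 with robust variances, 16 with array weights, 10 at adjusted p under 0.01 and 14 without SPC3833 arrays 2 and 4.

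Leaving out 1 array gave 467 to 967 changed genes, 218 to 458 higher, 235 to 549 lower, 49 to 61 large falls and 9 to 35 large rises.

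The replicate numbers were not taken to pair the arrays, a choice made in the plan because the numbers appear only in the titles. Deviations of same-numbered arrays correlated, across genes, at 0.159, 0.043, -0.030 and 0.145, so 2 of 4 pairs exceeded 0.1. Of the 8 arrays, 5 correlated best with their own number. The mean over all 24 assignments of the numbers was 2, and 3 of the 24 gave at least 5. The count is thus at most a weak hint of pairing, and whether the numbers pair the arrays stays open. With the replicate block 856 genes changed, 716 of them among the 911. The mean of several probe sets per gene was not run, since each ID has 1 probe set. Tests of gene lists were not run and Apob was not looked up, since the gene table used here gave no names for the IDs. Every probe set on its own is the comparison as reported. Whether low signal limited detection among dim genes was not tested. The dimmest 25% of genes, of which 0.411% changed, had a median SE of 0.115, against 0.103 for the brightest 25%.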

Other observations

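The tests in this part were chosen after the data were seen. SPC3833 array 4 held the highest SPC3833 value for 21 of the 25 genes that rose at least 2-fold. The median SD between SPC3833 mice was 0.448 for these genes and 0.217 without array 4, against 0.306 between saline mice. As these genes were called with array 4 included, the lower SD without it restates its high values and is no separate evidence. For the 50 genes that fell at least 2-fold the median SD was 0.202 between SPC3833 mice and 0.149 between saline mice.

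A hypothesis is that the size of the large rises differs between mice given SPC3833 more than that of the large falls. Each SPC3833 array was set against the mean of the other 3, over genes called without it. Its relative change for large rises was 0.79, 0.75, 0.51 and 1.20 on arrays 1 to 4 (range 0.690). For large falls it was 0.95, 0.85, 1.03 and 0.98 (range 0.183). The large rises that entered numbered 18, 23, 35 and 9, so the arrays were compared over different genes. Array 4 was also part of the mean for arrays 1 to 3. Over all called genes the contrast was smaller, with 0.83, 0.78, 0.61 and 1.12 for rises and 0.98, 0.69, 0.98 and 1.03 for falls. Offsets of a kind that quantile normalization removes are argued against as the whole cause. After it the ranges were 0.726 for large rises and 0.0944 for large falls. With array 1, 2 or 3 removed from every step, the range for large rises was at least 0.516. Ordinary variation of these genes between mice may account for the wider range of the large rises. Saline arrays ranged over 0.329 along the large rises and over 0.158 along the large falls. With 1 saline array removed from every step, they ranged over 0.182 to 0.339 for rises and 0.0737 to 0.179 for falls. Saline mice thus also ranged more widely along the rises, though barely without saline array 3 (0.182 against 0.179). With SPC3833 array 4 removed from every step, the ranges were 0.172 for rises, of which as few as 10 entered, and 0.265 for falls as deposited, and 0.208 for rises, of which as few as 6 entered, and 0.167 for falls after quantile normalization, so which was wider depended on the scaling.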
